A study of Cucumis sativus with 2 samples.

How the data were processed

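Leaves of 2 groups of cucumber plants, 30 mM NaHCO3 and 30 mM NaHCO3 with 100 µM sodium nitroprusside, each gave 1 library on day 12, per the labels. Poly(A) RNA was copied to cDNA on beads and cut at CATG by NlaIII, and MmeI then released tags of 21 bases that were amplified by PCR and sequenced on an Illumina HiSeq instrument, per the labels' protocols. How many plants went into each library was not given in the sources used here. The aligner, the reference gene set and the filters on tags were not given in the sources used here either, so no coordinates or genome build are reported.

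The authors deposited for each library a table of copy numbers, a raw count per distinct tag, and a gene table with a raw count per gene. The authors' TPM column, divides each count by all tags of the library's tag table and scales to 1000000, as the deposited values show. The gene count exceeds the copy number of the listed tag in some genes (it equals it in 69.1% and 67.5% of genes), so it is a sum over the tags of a gene. The deposited tables list only tags and genes with at least 2 copies, so a gene missing from a table may have had 0 or 1 copy, and the share of tags seen once, planned as part of the composition, could not be computed. In the tag table of the NaHCO3 library 214 lines had broken separators; these were read by the pattern of tag and number, and the total was 721 tags below the total implied by the authors' TPM. The listed tag lay at the first site in 77.0% and 75.5% of genes. Tags that hold a long run of A made up 2.14% and 2.83% of all tags.

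Product descriptions came from the deposited gene tables and name the best match in other organisms, not a tested function. Of 10035 gene identifiers, 0 matched the RefSeq gene table given for cucumber, which was therefore not used, and 251 genes had no description. Genes of a family can share a tag with a near copy, and how the authors assigned such tags is not given in the sources used here, so members of families such as peroxidases, elongation factors and tubulins are uncertain to that extent. The tags left over had no gene in these tables, and the gene results say nothing about them.

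Each gene with a summed count of at least 10 was tested with an exact two-sided binomial test of the SNP library's count given the sum over both libraries, with the expected share from the gene-assigned totals. The p-values were adjusted by the Benjamini-Hochberg method over all tested genes, and a gene was called at an adjusted p of at most 0.001 and at least 2-fold. The test covers counting error only. Ratios have exact 95% Clopper-Pearson intervals, counts have exact Poisson intervals, and shares have exact Clopper-Pearson intervals. For a gene not listed in 1 library the ratio was taken against a floor of 3 counts in that library, in list medians too. This ratio leaves out counting error. Where given, the 95% bound beside it is the lower end of the exact interval, with the missing count taken as 0. Levels are given as tags per 1000000 gene-assigned tags. Distinct tags were tested in the same way with the totals of the tag tables. The 38 gene lists were found by search terms in the descriptions. The median log2 ratio of each list with at least 5 tested members was placed among the medians of 10000 random lists of the same size, drawn to match deciles of mean expression, and called apart below percentile 2.5 or above 97.5; no p-value was computed across genes.

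The tests, lists, search terms and most alternatives were fixed before the data were examined, as was the rule for naming genes. The rule took the 10 genes called higher and the 10 called lower with a named product whose ratio interval lay farthest from 1, up to 3 called members per list with the highest mean level (or the highest member where none was called), and the 5 most abundant genes of each library, 105 genes in all, of which 98 were called. Other genes are named only to say what a member of a list does, or are said to be chosen after their values were seen.

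The procedure was tested on simulated counts for the SNP and NaHCO3 libraries. With counting error only, 6641 genes were tested; of genes changed 4-fold 77 of 99 were called, of those changed 2-fold 28 of 99, and of 6443 unchanged genes 0. With an added coefficient of variation between plants of 0.2, 90 of 6422 unchanged genes were called, and with 0.4, 904 of 6344. Of 100 random lists 1 lay outside the range.

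Alternatives were TMM factors from edgeR, median-of-ratios factors from DESeq2, the totals of the tag tables, other count filters and thresholds, and edgeR's exact test on the counts with an assumed biological coefficient of variation of 0.2 or 0.4, since no replicates allow it to be estimated. For lists, the filter, the matching and the mean in place of the median were varied, and for composition the deeper library was thinned to the total of the other. Chosen after seeing the data were the copy number of the listed tag alone, a correction for the number of G and C bases in the tags, and lists without members that a search term found by accident. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0.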

Results

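Transcript levels were measured by digital gene expression in leaves of the cucumber cultivar Jinchun 5 under alkaline stress, with and without a nitric oxide donor. The stress was 30 mM sodium bicarbonate (NaHCO3), and the donor was 100 µM sodium nitroprusside (SNP), a salt that releases nitric oxide and whose breakdown also sets free cyanide and iron. Leaves taken on day 12 gave 1 library per treatment, named here the NaHCO3 library and the SNP library. Each mRNA was counted through a tag of 21 bases, CATG and the 17 bases after it. With 1 library per treatment no difference has a replicate check, and each test compares these 2 libraries, not the treatments.

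The NaHCO3 library held 5907865 tags of 91773 distinct sequences, and the SNP library held 5789862 tags of 89864 distinct sequences. Of these, 1100066 tags (18.6%, exact 95% interval 18.59 to 18.65%) and 1262607 tags (21.8%, 21.77 to 21.84%) were assigned to genes. The gene tables listed 8766 genes in the NaHCO3 library and 8908 in the SNP library, of which 7639 were in both, and 2940 of the 10035 genes in either table had a description that names a product. The median gene had 17 and 16 tags. Intervals cover counting error only, since the tags were amplified without molecular identifiers.

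Among gene-assigned tags both libraries were led by Csa001020, the small subunit of Rubisco, the enzyme that fixes carbon dioxide in photosynthesis. It took 78286 tags per 1000000 gene-assigned tags in the NaHCO3 library (95% interval 77764 to 78811) and 77890 in the SNP library (77404 to 78379), a ratio of 0.995 (0.986 to 1.00; exact binomial test, adjusted p = 0.437). The same 5 genes took the most gene-assigned tags in each library, and the other 4 had no named product. Of these, Csa015782 passed the test at 2.13-fold higher in the SNP library (2.09 to 2.17), while Csa020862 was at 1.49-fold, Csa001535 at 1.21-fold and Csa021433 at 1.17-fold, all below the 2-fold minimum. The 10 most abundant genes took 17.8% of gene-assigned tags (17.70 to 17.84%) in the NaHCO3 library and 21.8% (21.75 to 21.89%) in the SNP library, or 3.31% and 4.76% of all tags. The 100 most abundant took 40.3% and 47.4% of gene-assigned tags, or 7.51% and 10.3% of all tags. The 10 most abundant tags, whether assigned to a gene or not, took 10.8% and 12.1% of all tags, more than the 10 most abundant genes. Some of the most abundant tags therefore belong to no listed gene, and the ranking of genes leaves them out.

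The comparison of the libraries asks which leaf transcripts differ when the nitric oxide donor is added to bicarbonate stress. Genes for defence enzymes and for stress-related transcription factors were lower in the SNP library, some by over 50-fold, while lists of plastid genes, chlorophyll synthesis, aquaporins and iron handling had medians moderately above those of random lists, with few of their genes called. Among the defence enzymes, chitinase Csa024219, which cuts the chitin of fungal walls, fell 67.0-fold (45.9 to 102), and the beta-1,3-glucanases Csa010901 and Csa001658, which cut glucans of fungal walls, fell 165-fold (70.3 to 509) and 115-fold (60.1 to 251). Among the higher genes, 3-hydroxy-methylglutaryl coenzyme A reductase Csa013488, the committed step of isoprenoid synthesis in the cytosol, rose 7.73-fold (6.41 to 9.39), and the NADH-dependent hydroxypyruvate reductase Csa014037, an enzyme of photorespiration, rose 7.84-fold (5.90 to 10.6).

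Of 6612 genes with a summed count of at least 10, 944 (14.3%) differed by the exact binomial test at an adjusted p of at most 0.001 and at least 2-fold. In the SNP library 290 were higher and 654 lower, so that 30.7% of the calls were higher. Scaling by all tags in place of gene-assigned tags shifts the median log2 ratio of all genes by +0.23 and makes the split nearly even, at 451 higher and 471 lower (48.9% higher). When a biological coefficient of variation of 0.4 between plants is assumed, 49 genes pass, 1 higher and 48 lower, and 15 of the 98 called genes in the set chosen for naming keep their call, all of them lower.

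The named products whose intervals lay farthest below 1 were, besides the chitinase and the glucanases, a putative catalytic protein Csa016464, which fell from 1233 to 5 tags (283-fold, 121 to 873), and a putative ATP binding protein Csa003754, which fell from 1167 to 8 (167-fold, 84.7 to 389). The STS14-like protein Csa003226 went from 341 to 3 tags, a ratio of 130 (44.3 to 636). A UDP-glucosyltransferase Csa015096 (313 tags), a NAC domain protein Csa000637 (237), an ascorbate oxidase Csa012200 (171) and a protein similar to the peach allergen family, Csa005055 (128), were not listed in the SNP library. Against a floor of 3 counts they were at least 119.7-fold, 90.7-fold, 65.4-fold and 48.97-fold lower. All 10 passed with the assumed coefficient of variation of 0.4 as well.

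The named products farthest above 1 included sufB Csa014344, a scaffold protein for iron-sulfur clusters in plastids, which rose 4.38-fold from 364 to 1828 tags (3.91 to 4.91). A plastid-lipid associated protein Csa022991 (48 tags), DIP-1 Csa018704 and inositol pentakisphosphate 2-kinase Csa017875 (30 tags each) were listed only in the SNP library, at least 13.9-fold, 8.71-fold and 8.71-fold higher. Sucrose phosphate phosphatase Csa002501, the last enzyme of sucrose synthesis, had 2 and 60 tags, a ratio of 26.1 (6.93 to 221). Epoxide hydrolase 2 Csa003084 rose 8.55-fold (4.60 to 17.6), a GA-like protein Csa015040 rose 6.02-fold (3.88 to 9.78) and an adenosine monophosphate binding protein Csa014815 rose 5.54-fold (3.78 to 8.37). None of these 10 passed with the assumed coefficient of variation of 0.4.

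**Figure D1:**
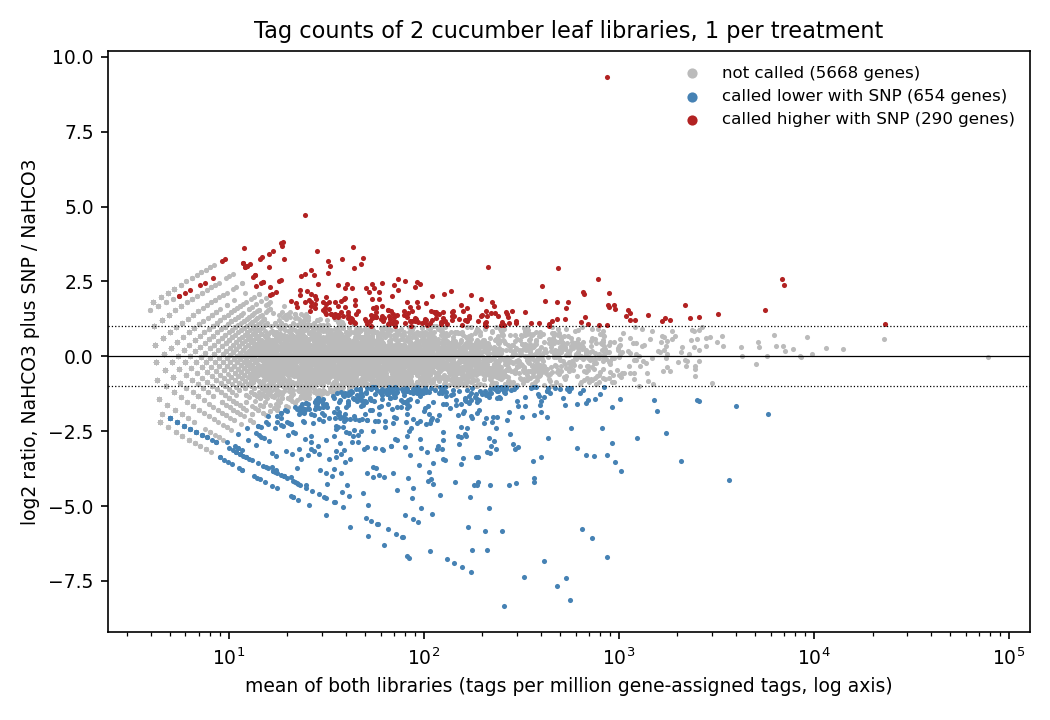
Log2 ratio of the SNP library to the NaHCO3 library (vertical axis) against the mean of both libraries in tags per 1000000 gene-assigned tags (horizontal log axis), 1 point per tested gene. Dotted lines mark 2-fold; 290 genes were called higher (red) and 654 lower (blue), and beyond 4-fold there were 91 higher and 361 lower.

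**Figure D2:**
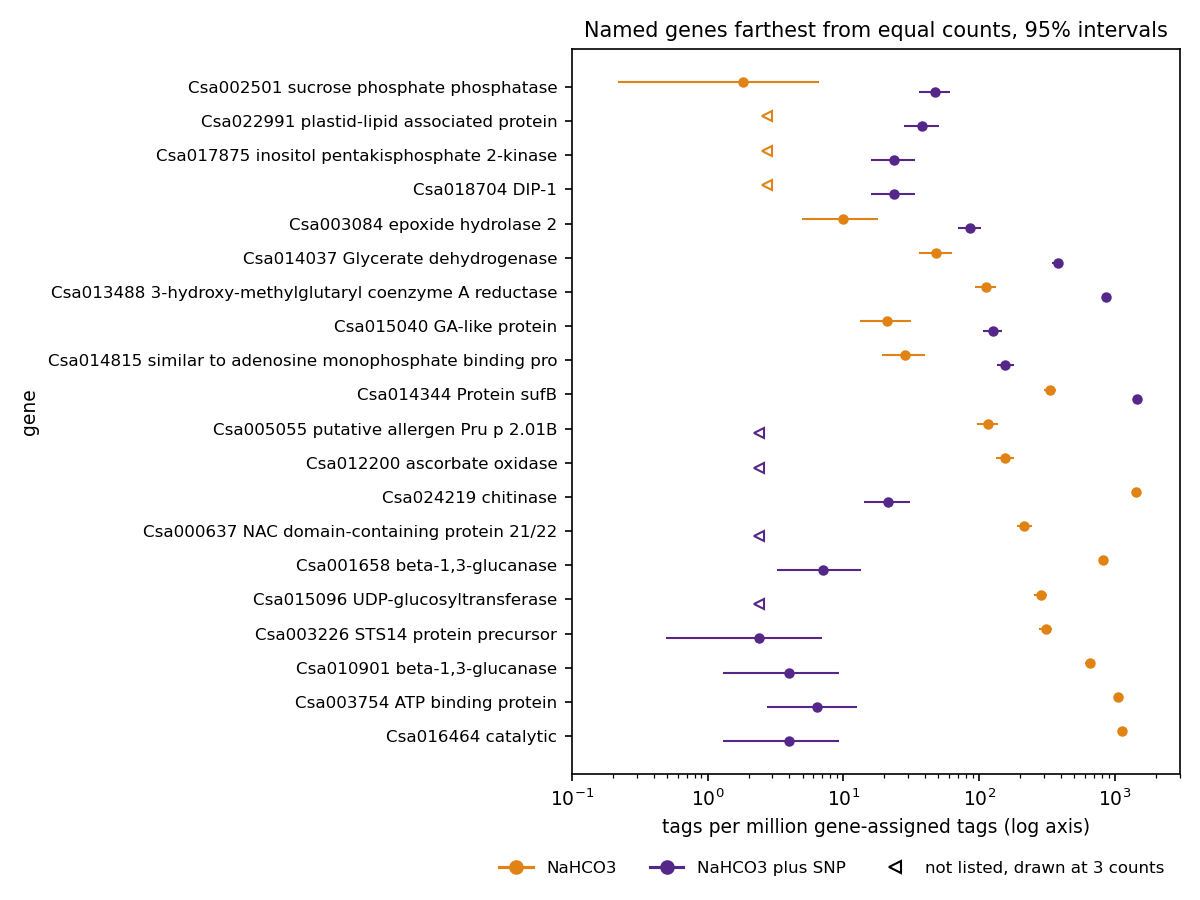
Tags per 1000000 gene-assigned tags (horizontal log axis) in the NaHCO3 library (orange) and the SNP library (purple) for the 10 named products called higher and the 10 called lower with intervals farthest from 1. Bars are 95% counting intervals and open triangles mark genes not listed in a library, drawn at 3 counts; chitinase Csa024219 goes from 1577 to 27 tags.

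Across 38 gene lists fixed before the data were examined, 35 had at least 5 tested members, and the median log2 ratio of 16 lay outside the central 95% of 10000 random lists matched on expression, 8 above and 8 below; 1.75 would lie outside by chance if genes were independent. Some lists share members, such as Csa017144 in those of ethylene and of ERF and AP2 factors, so the 16 are not separate results. Counts adjusted over the list alone were the same as over all genes except for the pathogenesis-related proteins (11 lower) and the ERF and AP2 factors (1 higher, 6 lower). With only the listed tag of each gene counted, the lists of photosystems (percentile 93.4), the Calvin cycle (92.1), antioxidant enzymes (94.8), cell wall (92.6), plastid ribosomal proteins (97.2) and ethylene (4.94) lie within the random range, and aquaporins do so against unmatched random lists (97.4). The listed-tag setting also leaves out genes whose listed tag differs between the libraries, so lists can lose members (photosystems 11 tested in place of 14). When scaled by all tags, receptor-like kinases gain 2 higher calls, and 1 each is gained by jasmonate, auxin, gibberellin and brassinosteroid, ERF and AP2, phloem and circadian lists, where none was called higher.

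The lists that lay lowest were those of defence. Among class III peroxidases, secreted enzymes that use hydrogen peroxide at the cell wall, 5 of 6 tested genes fell and none rose (median log2 ratio -3.70, percentile 0). With TMM factors or when scaled by all tags 4 fell. Peroxidase Csa010531 fell 17.7-fold, from 7681 to 499 tags (16.1 to 19.4), Csa010527 fell 56.6-fold (29.6 to 125) and peroxidase 5 Csa010163 fell 24.6-fold (13.8 to 48.2). Of 14 pathogenesis-related proteins 9 fell and none rose (median -2.22, percentile 0), or 7 when scaled by all tags. Over the 7 genes with a summed count of at least 50 the median is -5.53. Glutathione transferases, which conjugate glutathione to reactive compounds, had 5 of 12 lower, or 4 when scaled by all tags. But their median of -0.67 (percentile 2.76) was within the random range. They lay below it with the mean (-1.49, percentile 0.190) and with the correction for G and C bases (-0.69, percentile 2.47). The transferase Csa017288 fell 19.6-fold (13.3 to 30.0) and Csa001819 fell 8.56-fold (4.78 to 16.7). Csa000193, with 126 tags and not listed in the SNP library, was 48.2-fold lower against the floor (95% bound 38.6). Phenylpropanoid and flavonoid genes had 4 lower and 1 higher of 21 (median -0.03, percentile 58.5), or 2 lower when scaled by all tags (median 0.19). Cinnamyl alcohol dehydrogenase Csa003202, an enzyme of lignin synthesis, had 55 tags and was not listed in the SNP library. It was 21.04-fold lower against the floor (95% bound 16.5), and phenylalanine ammonia-lyase Csa002864 fell 4.59-fold (2.33 to 9.86). The list of phloem proteins was also low (median -1.57 over 6 genes, percentile 0.470). Its search terms take in any lectin as well, so its members need not be markers of sieve and companion cells. The 1 call was the 26 kDa phloem protein Csa001568, which fell 2.20-fold (1.86 to 2.60), a call that is lost when scaled by all tags.

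Families of transcription factors that act in stress responses were low as well. Of 10 WRKY factors 7 fell, or 6 with TMM factors or when scaled by all tags, and none rose (median -1.66, percentile 0.01). WRKY gene Csa004896 fell 11.3-fold from 4212 to 429 tags (10.2 to 12.5), Csa005866 fell 19.9-fold (14.0 to 29.1) and Csa002274 fell 3.15-fold (2.66 to 3.75). Of 14 NAC factors 5 fell (median -1.51, percentile 0; -2.69 over the 6 with a summed count of at least 50), among them Csa017274 at 10.2-fold (8.19 to 12.8) and the NAM-like Csa020414 at 4.10-fold (3.33 to 5.08). Of 15 ERF and AP2 factors 5 fell, or 4 with TMM factors or when scaled by all tags (median -1.07, percentile 0.110). The ethylene responsive factor 1a Csa017144 fell 4.64-fold (3.37 to 6.50) and the RAP2-like Csa008584 fell 2.42-fold (1.697 to 3.48). MYB factors stayed within the random range (2 of 15 lower, median -0.12, percentile 48.1), or 1 lower when scaled by all tags (median 0.10), with Csa008970, at 15 tags and not listed in the SNP library, at least 5.74-fold lower.

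In hormone and signalling lists, 6 of 13 genes of ethylene synthesis and response fell (median -1.15, percentile 0.045; within the range with the mean, -0.81, percentile 6.39). ACC oxidase, which makes ethylene in its last step, was abundant: Csa023227 fell 3.77-fold from 10075 to 3066 tags (3.62 to 3.93), Csa007981 fell 3.90-fold (3.31 to 4.61) and Csa004025 fell 2.82-fold (2.44 to 3.27). The 1 higher member, Csa006349, is methylenetetrahydrofolate reductase, an enzyme of folate metabolism. Ethylene responsive factors, such as Csa017144, stand in this list and in that of ERF and AP2 factors, so these are not separate results. Of 28 calcium signalling genes 8 fell, or 3 when scaled by all tags (median -0.68, percentile 0.40), with the calcium-dependent protein kinase Csa000481 at 4.35-fold (3.57 to 5.34). Of 35 receptor-like kinases and resistance proteins 9 fell, or 8 with TMM factors or when scaled by all tags. Still, the median of -0.41 (percentile 6.10) was within the random range. It lay below the range with no filter (-0.42, percentile 2.16), the mean (-1.16, percentile 0), the listed tag (-0.67, percentile 0.505) and the correction for G and C bases (-0.53, percentile 1.12). Receptor kinase Csa010061 had 184 and 2 tags, a ratio of 106 (28.8 to 878), the LRR kinase Csa016594 fell 14.9-fold (8.09 to 30.6) and Csa018300 fell 3.89-fold (2.92 to 5.25).

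The medians of the other hormone lists lay within the random range, or the lists had too few members. Of 18 gibberellin and brassinosteroid genes 5 fell, or 4 with TMM factors or when scaled by all tags (median -0.33, percentile 17.2). But the list lay below the range with the mean (-0.89, percentile 0.820) and at a summed count of at least 50 (-2.11, percentile 0.090). Of the 5 lower genes, 4 are receptor kinases of the BRI1 and BAK1 type, which act in both brassinosteroid signalling and immunity. They also stand in the receptor kinase list. Csa005406 fell 6.24-fold (3.64 to 11.4), Csa016541 fell 8.84-fold (4.56 to 19.2), and Csa010511 had 52 and 3 tags, a ratio of 19.9 (6.44 to 99.6). Abscisic acid and dehydration genes had 3 lower and 1 higher of 14 (median -0.19, percentile 41.3; 0.03 when scaled by all tags), including type 2C protein phosphatases in both directions: Csa018274 fell 4.29-fold (2.68 to 7.13), Csa003318 fell 2.73-fold (1.98 to 3.79) and Csa021128 rose 3.65-fold (2.25 to 6.19). None of 7 auxin response genes passed (median 0.39, percentile 88.0); Aux/IAA gene Csa018571 had a log2 ratio of 0.33 (0.17 to 0.50). Of 4 jasmonate and lipoxygenase genes 1 fell, lipoxygenase Csa009893 at 3.98-fold (3.14 to 5.10), with a list median of -0.23.

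Photosynthesis and plastid lists lay on the other side, with shifts far smaller than those of defence. For photosystems and light harvesting, 13 of 14 log2 ratios were above 0 (median 0.47, percentile 99.3), and the 1 call (5 when scaled by all tags) was the chlorophyll a/b binding protein Csa018819, an antenna protein, which rose 2.29-fold from 1227 to 3226 tags (2.14 to 2.45). Of 9 genes of chlorophyll biosynthesis 2 rose (median 0.65, percentile 99.2): magnesium-protoporphyrin cyclase Csa013740 at 2.52-fold (2.01 to 3.16) and glutamyl-tRNA reductase Csa018608, the controlled entry step, at 2.24-fold (1.82 to 2.77). Of 7 Calvin cycle genes 2 rose (median 0.68, percentile 98.6). The list falls within the range with no filter (0.45, percentile 96.6), unmatched random lists (percentile 97.4), the mean (0.51, percentile 96.7) and the correction for G and C bases (0.56, percentile 96.4). The higher genes were Rubisco activase Csa017702, which keeps Rubisco active, at 2.25-fold (2.10 to 2.41) and the Rubisco-binding chaperonin Csa013004, which folds proteins, at 2.08-fold (1.58 to 2.77). Of 8 plastid ribosomal proteins 2 rose (median 0.62, percentile 98.6; 0.35, percentile 88.5, at a summed count of at least 50): the plastid-specific protein Csa017277 at 4.50-fold (3.36 to 6.12) and L34 Csa000658, with 15 tags in the SNP library and not listed in the NaHCO3 library, at least 4.36-fold. None of 4 genes of chlorophyll breakdown and senescence passed (median 0.09); red chlorophyll catabolite reductase Csa018122 had a log2 ratio of 0.66 (0.49 to 0.84). Cytosolic ribosomal proteins had a median of -0.34 (percentile 5.31) over 40 genes with 1 call (2 when scaled by all tags), S27 Csa012641, which rose 3.30-fold (2.57 to 4.28).

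Antioxidant enzymes, iron handling and water channels were also above the random lists. Of 17 antioxidant enzymes 2 rose (median 0.42, percentile 99.3; 0.31, percentile 97.0, at a summed count of at least 50, and 0.34, percentile 97.465, with the correction for G and C bases, both within the range). These were iron superoxide dismutase Csa016620, which removes superoxide in plastids, at 2.28-fold (1.77 to 2.96) and the plastid peroxiredoxin Q Csa005664 at 2.39-fold (1.64 to 3.54). The iron handling list had 3 of 12 higher (median 0.71, percentile 99.7), or 6 when scaled by all tags. The 3 are oligopeptide transporters (Csa022463 at 2.26-fold, 1.81 to 2.83; Csa001164 at 2.56-fold, 1.72 to 3.90; Csa012782 at 2.36-fold, 1.52 to 3.79), a family that carries peptides as well as metal chelates. All 10 aquaporins had log2 ratios above 0 (median 0.53, percentile 99.3), and the 1 call (2 when scaled by all tags) was the tonoplast intrinsic protein Csa011871, which rose 2.09-fold (1.89 to 2.31). Cell wall genes were mixed in their calls, 4 higher and 3 lower of 27 (median 0.44, percentile 99.7). The list falls within the range with no filter (0.021, percentile 81.7), the mean (0.087, percentile 90.6) and the correction for G and C bases (0.20, percentile 92.6). Expansin Csa016096, which loosens walls, rose 2.17-fold (1.83 to 2.58) and the cellulose synthase-like Csa019366 rose 2.53-fold (1.98 to 3.25), while 1 of the lower members, Csa016194, is a polygalacturonase-inhibiting protein, a class that acts against fungal enzymes. Ion and proton transport had 4 of 26 higher and none lower (median 0.26, percentile 95.3; 0.39, percentile 99.3, with the mean), with the vacuolar proton pump subunits c Csa003911 at 2.56-fold (2.34 to 2.80) and A Csa009852 at 2.75-fold (2.26 to 3.36) and the sodium/proton antiporter-like Csa008770 at 2.17-fold (1.84 to 2.56); the other, Csa000453, is a bile acid cotransporter homolog.

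**Figure D3:**
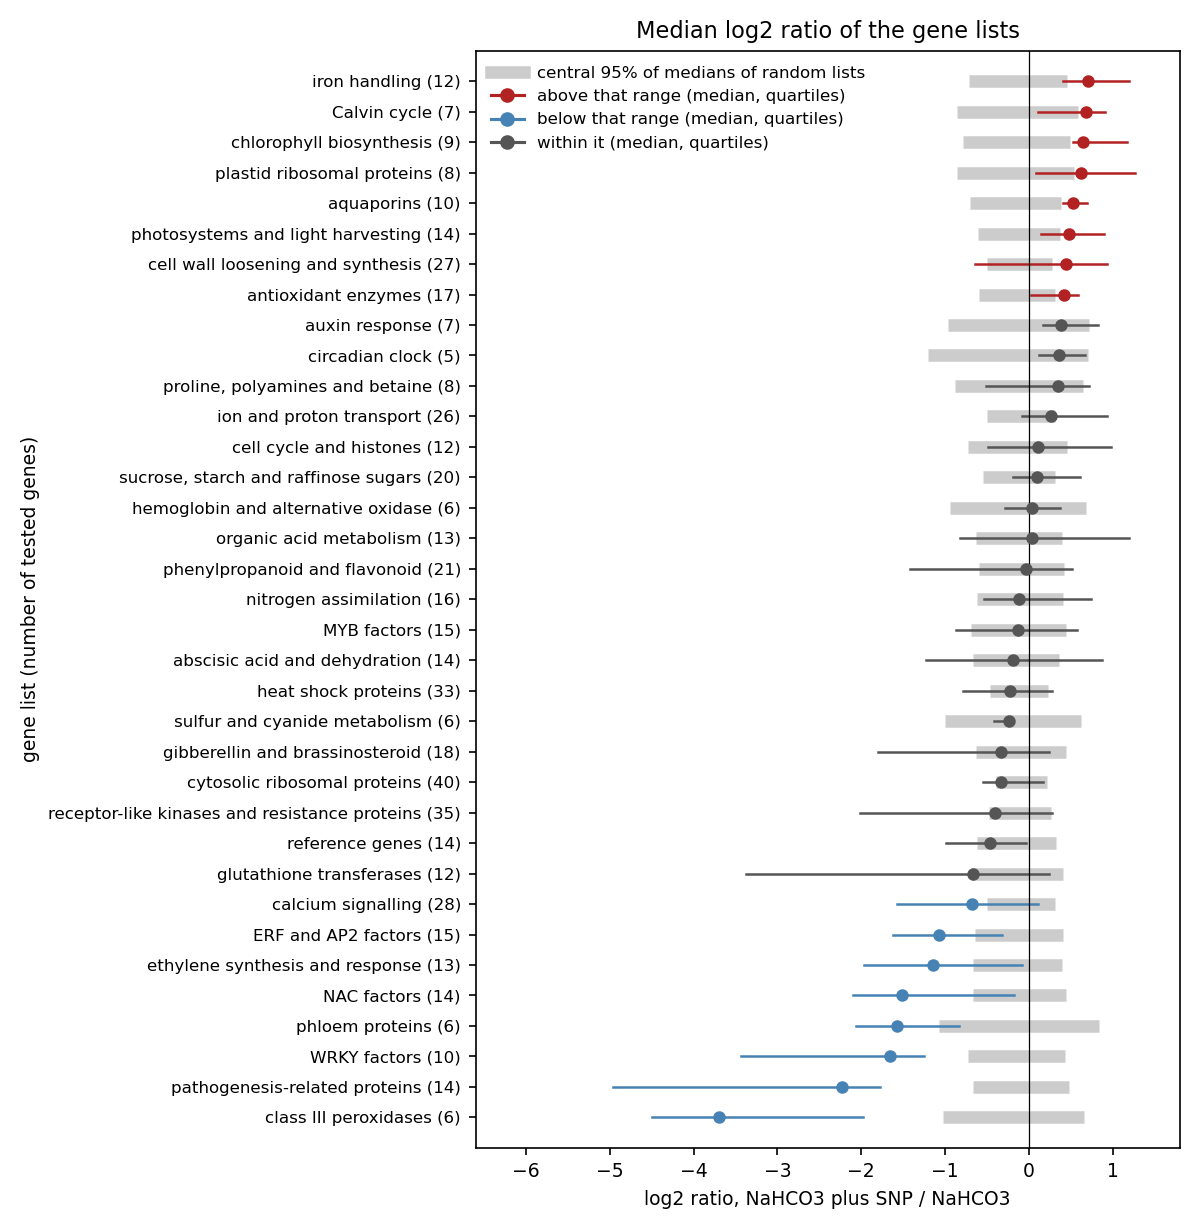
Median log2 ratio of the SNP library to the NaHCO3 library (points) with the quartiles of the members (thin lines) for the 35 lists with at least 5 tested genes. Grey bars span the central 95% of medians of 10000 expression-matched random lists; 8 lists lie above (red) and 8 below (blue), with class III peroxidases lowest at -3.70.

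Medians of the lists of primary metabolism lay within the random range, except 1 at a higher count filter. Nitrogen assimilation had 2 higher and 2 lower of 16 (median -0.11, percentile 49.3), or 3 and 1 when scaled by all tags (median 0.11). At a summed count of at least 50 its median is 0.51, at percentile 97.6. Nitrite transporter Csa002657 rose 4.60-fold (3.08 to 7.09) and nitrate transporter Csa005174 fell 3.77-fold (2.78 to 5.18). Nitrate reductase Csa008225, chosen after its values were seen, rose 5.31-fold from 10 to 61 tags. Among genes of sucrose, starch and raffinose sugars 3 rose and 2 fell of 20 (median 0.09, percentile 81.2): granule-bound starch synthase Csa015414 rose 2.45-fold (1.87 to 3.24), galactinol synthase Csa000881, the entry to raffinose sugars, fell 16.8-fold from 759 to 52 tags (12.6 to 22.6), and trehalose-6-phosphate synthase Csa018212 fell 2.58-fold (2.21 to 3.02). Organic acid metabolism had 3 higher and 1 lower of 13 (median 0.04, percentile 65.9), or 4 and 0 when scaled by all tags, with cytosolic malate dehydrogenase Csa016962 at 3.06-fold (2.69 to 3.50) and the glyoxysomal form Csa012154 at 2.08-fold (1.74 to 2.496) higher. In the list of proline, polyamines and betaine, arginine decarboxylase Csa020865, an entry to polyamine synthesis, fell 2.73-fold (2.54 to 2.94) as the 1 call of 8 (median 0.35, percentile 88.1; -0.33 over the 5 with a summed count of at least 50).

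Of 33 heat shock proteins and chaperones 5 fell and 1 rose (median -0.22, percentile 23.0), or 3 and 1 when scaled by all tags (median 0.01). Heat shock protein 70 Csa012806 fell 6.64-fold (5.98 to 7.39) and its cognate Csa010385 fell 2.84-fold (2.68 to 3.01); Csa008853, also lower, is a heat shock factor, a regulator of these genes. Mitochondrial alternative oxidase Csa004163, which bypasses the cyanide-sensitive step of respiration, fell 5.22-fold from 1510 to 332 tags (4.63 to 5.90) and was the 1 call of 6 in the list of hemoglobin and alternative oxidase (median 0.04, percentile 61.5). In sulfur and cyanide metabolism 1 rose and 1 fell of 6 (median -0.23, percentile 39.3), cysteine synthase Csa000814 at 4.94-fold higher (2.05 to 14.4) and sulfate transporter Csa008258 at 2.24-fold lower (1.63 to 3.10), the latter lost when scaled by all tags. Cell cycle and histone genes had 2 higher of 12 (median 0.11, percentile 77.1; 0.48, percentile 97.51 and just outside the range, at a summed count of at least 50): histone H3 Csa010505 at 2.45-fold (1.54 to 3.99) and FtsZ Csa011989, which divides plastids rather than cells, at 3.17-fold (2.10 to 4.91). No circadian clock gene of 5 passed (median 0.37, percentile 89.5); CONSTANS-like Csa015907 had a log2 ratio of -0.55 (-0.81 to -0.30). The list of epidermis and cuticle had 1 gene, below the minimum count. Of 14 genes often used as references in quantitative PCR 4 fell, or 2 with TMM factors or when scaled by all tags (median -0.46, percentile 9.66). Among them was the elongation factor 1-alpha gene Csa012549, 18.7-fold lower (13.5 to 26.7).

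The tags were also compared without any assignment to genes. Of 45821 distinct tags with a summed copy number of at least 10, 1606 were higher and 3057 lower in the SNP library by the same test, 4663 in all (10.2%), against 14.3% of genes. For 5048 genes whose listed tag did not differ between the gene tables, the copy number of that tag could be tested by itself. These include genes missing from either the NaHCO3 or the SNP gene table, whose listed tag was also missing from that library's tag table. Of 696 of the 5048 genes that were called in the gene comparison, 610 passed in the same direction and 0 in the opposite direction. But over the 6612 tested genes the listed tag held a median of 99.6% of a gene's count. The listed-tag result thus repeats nearly the same counts and is not a separate check of the calls.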

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

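The tests of base errors and of similar genes were chosen only after these pairs had been seen; the test on rarer pairs was set before its result was seen.

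The tag tables hold a signal that the gene comparison does not use: pairs of tags that differ at 1 of their 21 bases and in their shares between the libraries. Of 326 pairs 1 base apart (each tag with at least 50 copies summed over the libraries, at least 10% of the pair and in no other pair, at least 40 copies of the pair in each library and no run of 8 A), 31 differed in share by at least 20 percentage points at an adjusted p of at most 0.001 in Fisher's exact test. In 5 of the 31 each library held a different tag almost alone (98% or more), in 15 the NaHCO3 library held a mixture of 35% to 65% and the SNP library 1 tag, and in 6 the reverse. The tag CATGGGTAAAGTACACGGATC had 1230 copies in the NaHCO3 library and was not listed in the SNP library. Its T7G variant CATGGGGAAAGTACACGGATC, with position 1 at the C of CATG, was not listed in the NaHCO3 library and had 1316 copies in the SNP library. The pair CATGCAGAATGTAAATGTTTC and CATGTAGAATGTAAATGTTTC (C5T) had 1705 and 1462 copies in the NaHCO3 library and 2 and 2530 in the SNP library.

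A base error cannot outnumber the tag it came from, yet in 14 of the 31 pairs each tag was the commoner one in 1 library, with both 95% intervals beyond 50%, which argues against base errors in those. In the other 17 the rarer tag held at least 23.1% of the pair in 1 library (smallest lower 95% bound). Of all possible 1-base variants of the 1000 most abundant tags 99% held at most 0.282%. But pairs were kept only where the shares differed by at least 20 percentage points. A rarer tag near the error level could thus not be among them, and for these 17 pairs the comparison cannot decide on base errors. Similar genes expressed independently stay open. Between 40% and 60% lay 77.8% of the shares between 20% and 80% (21 of 27, exact 95% interval 57.7 to 91.4%). No spread known to come from similar genes was measured to set this against. Near-equal mixtures were also frequent among pairs that did not pass as differing. Among the 326 pairs, 100 such pairs lay at 35% to 65% in both libraries, and their origin was not tested. Plants that differ in genotype behind the libraries remain a candidate explanation, with pairs standing for alleles, but the test on 140 rarer pairs (20 to 49 copies per tag) left only 2 mixtures to judge, of which 0% were near equal (0 to 84.2%), too few to decide. With 1 library per treatment, a genotype difference of this kind and the treatment cannot be told apart in these data. A tag listed for a gene was part of 1 of the 31 pairs and of 17 of the 326.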

How the results depend on the processing

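The results with only the listed tag counted, the correction for G and C bases and the lists without accidental members were chosen only after the results were seen. No paired analysis was possible because each treatment has 1 library, and for the same reason no replicate could be left out. The share of tags seen once was not run. The count of called genes was 944; it was 1499 with no fold minimum, 452 at 4-fold, and 321 and 49 with edgeR's exact test at an assumed coefficient of variation of 0.2 and 0.4. The 290 higher genes became 451 with tag totals and 459 at an adjusted p of at most 0.05. They became 534 with no fold minimum, 91 at 4-fold, and 53 and 1 with the assumed variation. With only the listed tag there were 187, but over 5048 genes in place of 6612. Those 5048 genes hold 696 of the 944 calls. The 654 lower genes became 361 at 4-fold and 268 and 48 with the assumed variation. TMM factors gave 334 higher and 568 lower, median-of-ratios factors 335 and 567, no filter 278 and 629, and a summed count of at least 50 gave 253 and 524. All 290 higher calls remained under the other 3 scalings, and 568, 567 and 471 of the lower calls, with 0 reversed. Of 4663 called tags (1606 higher, 3057 lower), an adjusted p of at most 0.05 gave 8042 (3153 and 4889), and the other tag settings stayed within 1.5 times. With only the listed tag, and the fewer genes it leaves, some lists were no longer apart: photosystems 0.33, Calvin cycle 0.40, antioxidant enzymes 0.32, ethylene -0.62, cell wall 0.25 and plastid ribosomal proteins 0.60, while receptor-like kinases became so at -0.67. With no filter, the Calvin cycle (0.45) and cell wall (0.021) lists were no longer apart and receptor-like kinases (-0.42) were. Against unmatched random lists the Calvin cycle (0.68) and aquaporins (0.53) came just inside. With the mean, the Calvin cycle (0.51), ethylene (-0.81) and cell wall (0.087) lists were no longer apart, and glutathione transferases (-1.49), ion transport (0.39), gibberellin and brassinosteroid (-0.89) and receptor-like kinases (-1.16) became so. With the correction for G and C bases, the Calvin cycle (0.56), antioxidant (0.34) and cell wall (0.20) lists were no longer apart, and glutathione transferases (-0.69) and receptor-like kinases (-0.53) became so. At a summed count of at least 50, antioxidant enzymes (0.31) and plastid ribosomal proteins (0.35) were no longer apart, and nitrogen assimilation (0.51), gibberellin and brassinosteroid (-2.11) and cell cycle (0.48) became so. The cause was not tested for any of these. Medians within the random range also changed sign: proline (-0.33) at a summed count of at least 50, phenylpropanoid with TMM factors (0.063) and the listed tag (0.10), MYB with the listed tag (0.17), hemoglobin with the mean (-0.11) and the G and C correction (-0.14), and nitrogen (0.044) and sulfur (0.0031) with the mean. The lists of chlorophyll biosynthesis, iron handling, peroxidases, pathogenesis-related proteins, WRKY, NAC, ERF and AP2 factors, calcium signalling and phloem proteins stayed apart in every alternative that could be run for them, and 5 lists without accidental members kept their side. Thinning the NaHCO3 library to the other total moved none of its shares beyond the interval. Of 105 named genes, 10 lost their call with TMM factors and 13 with tag totals; with the assumed variation of 0.4, 83 did, so that 15 of 98 calls remained. In simulated counts with that variation 904 of 6344 unchanged genes were called, close to the 944 called here. The direction and size of the simulated calls were not recorded, so only these totals can be compared. Of 99 genes changed 2-fold in counts with counting error only, 45 passed the adjusted p and 28 also reached the fold minimum.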

Other observations

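The gene ontology terms and the tests on G and C content, tag variants and plants were chosen only after the results were seen. The test of the freed share replaced an earlier form, which could not decide, and was set before its own result was seen.

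Gene ontology terms in the deposited gene tables with 15 to 400 tested genes, 168 in all, had 20 medians above and 10 below the central 95% of matched random lists, where 8.4 would lie outside by chance if genes were independent. Terms overlap, so these are not 30 separate results. On the higher side, chloroplast thylakoid had 20 of 151 higher and 4 lower (median log2 ratio 0.43, percentile 100), plastid stroma 15 higher and 5 lower of 191 (0.37, percentile 100) and plastid envelope 16 higher and 3 lower of 163 (0.34, percentile 100). Porphyrin biosynthesis had 3 higher and 1 lower of 20 (0.55, percentile 99.95), starch metabolic process 2 higher of 15 (0.70, percentile 99.9) and iron-sulfur cluster binding 2 higher of 22 (0.47, percentile 99.5). The extracellular region had 8 higher and 8 lower of 99, yet its median of 0.32 lay at percentile 99.99. Response to reactive oxygen species lay above too (0.66 over 15 genes, percentile 99.7). Antioxidant activity lay within the range, with 2 higher and 4 lower of 20 (-0.035, percentile 58.6). On the lower side, protein kinase activity had 31 of 128 lower and 5 higher (-0.39, percentile 0.330), DNA-binding transcription factor activity 23 lower and 5 higher of 114 (-0.34, percentile 1.41), and response to carbohydrate stimulus 6 lower of 28 (-0.65, percentile 0.545). The medians of the terms for defence lay within the random range, with calls in both directions: defense response had 3 higher and 12 lower of 65 (-0.092, percentile 52.3), and response to other organism 2 higher and 12 lower of 81 (0.044, percentile 90.1).

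The gene with the largest ratio of all had no named product. Csa015346, chosen after its values were seen, was not listed in the NaHCO3 library and had 2202 tags in the SNP library, at least 639.5-fold higher. Its listed tag CATGAAAGAGAGCTGATTATG was likewise listed only in the SNP library, with 2182 copies.

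The lists of peroxidases, pathogenesis-related proteins, WRKY and NAC factors hold 44 tested genes, of which 26 fell and none rose. A bias by G and C content is argued against, since after correction the highest of the 4 percentiles was 0.01. Loss of tags to 1-base substitutions, as alleles can cause, is argued against too, for 21 of the 26. These were 2-fold lower in their listed tags when scaled by all tags, and the other called members were not judged. Among the 21 members, 13 had no such variant in either tag table, and 8 had variants. Other kinds of difference within a tag were not searched. With the variants added 0 came below 2-fold. Loss of a CATG site was not tested. Differences between plants unrelated to the donor remain open, since 7 of the 26 calls are kept at an assumed coefficient of variation of 0.4 but 1 library per treatment cannot exclude a shared difference.

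The lists of chlorophyll biosynthesis, photosystems and aquaporins lay above the random lists. After correction for G and C bases the lowest of their percentiles was 98.6, which argues against that bias in these lists. The test and these lists were chosen after the results were seen. The Calvin cycle, antioxidant and cell wall lists, also above the random lists, came within the range with this correction. The correction thus says nothing for the higher lists as a group. The genes called lower went from 16.8% of gene-assigned tags to 4.06%, and the share they freed would raise every other gene by 0.21 on the log2 scale. Such a rise would lift all these genes alike, yet among random lists drawn only from genes not called lower the lowest percentile of the 3 lists was 98.28, which argues against the freed share as the whole cause. How the listed tags were assigned, or the loss of members, may still matter for the photosystem list. It is at percentile 93.4 with the listed tag alone (0.33 over 11 members in place of 14). A difference between the plants of the 2 treatments was not tested for these lists.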
